A study of Mus musculus with 26 samples.

How the data were processed

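RNA of 13 mouse cell lines was profiled on Illumina MouseRef-8 bead arrays, 2 arrays per line. Per the labels' protocols, total RNA was amplified to labelled cRNA with a TotalPrep kit, with in vitro transcription for 14 h. The labels call the 2 arrays of a line biological replicates without saying that they are separate cultures. The line or clone was taken as the unit of replication, as fixed before the data were examined. The number of genes at least 2-fold apart between the arrays of a line was 0 in each iPSC[GSC] line and at most 10 in any line. One description of an adult GSC array carries the other array's number, and its title was used.

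The deposited table of 25697 probes holds for each array a signal intensity and a detection p-value. Per the submitters' processing notes these intensity values were exported from BeadStudio 3.2. RMA and lumi are also named there, without versions, roles or order. The detection p-value of each probe is given as deposited in the same table, per the file headers, and says how far the probe stands above the negative controls. A matrix of normalised values was also deposited by the authors. Its values are read as log2 from their range (0.20 to 14.16), all arrays have the same distribution, and the authors' steps are not stated beyond those notes. This matrix served as an alternative only.

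Probes were named through the deposited Entrez identifiers and accessions with a mouse gene table on assembly GRCm38.p6, used for names and neighbouring genes only. Of all probes 23978 had a single symbol and 1719 none, and symbols were matched by Entrez identifier for 23962, by accession for 9 and kept from the file for 7. Intensities were background-corrected with the detection p-values, quantile-normalised and log2-transformed with neqc (offset 16) in limma 3.58.1, with statmod 1.5.0 and R 4.3.3. Probes with a detection p under 0.01 on at least 2 arrays were kept (14517), and a gene was represented by its kept probe with the highest mean level, leaving 9840 genes. A gene at background on every array of a side was given a lower bound for its fold, taking as the level of that side the higher of its own signal and the array's detection floor.

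Depth on an array is signal over background. The background median was 79.4 to 113.4 and the median signal 1.109 to 1.276 times background. The 95th percentile stood at 8.86 to 26.24 times background, highest on the MEF arrays. Between 38.9% and 47.0% of probes were detected per array. Genes near background have compressed differences.

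Comparisons, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. For comparisons among iPSC[GSC] and gPSC clones, limma was fitted to 8 clone means with method and origin as cell means. For the 8 comparisons involving GSC, MEF, ESC or iPSC[MEF], it was fitted to the 26 arrays in 9 cell types with the line as a random block (consensus correlation 0.812). Calls are Benjamini-Hochberg adjusted p under 0.05 in limma. Lists were tested with cameraPR in limma at a preset inter-gene correlation of 0.01 and again with an estimated one, adjusted over 20 lists per comparison. A list call lost with the estimated correlation is given with that p. The estimate had no lower limit. An estimate below 0.01 makes p smaller, so a p that fell with it is not a stricter check. Distances between clones were tested by exact permutation over 35 splits.

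Genes measured of each list were: pluripotency network 27 of 32, spermatogonial stem cell 23 of 32, germ cell, piRNA and meiosis 26 of 42, fibroblast and extracellular matrix 37 of 41, testis somatic cell 9 of 25, paternally expressed imprinted 16 of 32, maternally expressed imprinted 18 of 32, DNA methylation enzymes 14 of 24, primed epiblast 15 of 19, mesoderm and endoderm 23 of 32, neural and ectoderm 14 of 27, trophoblast 16 of 20, two-cell-like state 8 of 21, sex-linked 10 of 16, p53 target and senescence 20 of 24, interferon-response 21 of 27, glycolysis 19 of 22, oxidative phosphorylation 32 of 36, immediate-early and heat shock 23 of 26, and reprogramming factors 4 of 4. Genes were named by rule: per comparison up to 8 higher and 8 lower genes with the largest log2 difference among those called that separate every line (or array, where a side has 1 line) of the sides, and where none was called the 5 with the smallest p. Pou5f1, Nanog, Sox2 and Klf4 were always named, with up to 4 members of each list whose set test or members passed. Where text names other genes it says that they were chosen after their values were seen.

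Simulated data gave each gene a single mean level in all cell types, except for the genes changed on purpose. The real contrasts of pluripotent cells with GSC or MEF differ far more (4721 calls in iPSC[GSC] against GSC, 3136 in iPSC[MEF] against MEF). Simulated shares of unchanged calls need not hold there. On these simulated data the fits were tested with 67, 67 and 66 of 9840 genes changed 2-fold, 4-fold and 8-fold. In iPSC[GSC] against gPSC the clone-mean fit recovered 58.2%, 94.0% and 93.9% of them, and 10 of 174 calls were unchanged genes. In the neonatal comparison it recovered 37.3%, 76.1% and 83.3%, with 4 of 135. The random-block fit called too many unchanged genes: 171 of 327 calls in iPSC[GSC] against ESC, 239 of 422 against GSC, 193 of 335 between the GSC lines and 230 of 380 in iPSC[MEF] against MEF. With 1 mean per line these were 5 of 112, 7 of 143, 5 of 95 and 7 of 96. The random-block fit was kept as designed, its adjusted p is too small in the 4 comparisons simulated and may be so in the other 4, which share the fit, and the count with 1 mean per line stands beside each. Set tests there rest on the same fit, and those lost with 1 mean per line are named with that p or its range. Where both sides hold 1 line (the GSC lines, iPSC[MEF] against MEF or ESC) the spread between lines is taken from the other cell types, so these tests compare single lines and not kinds of cell. With 1 mean per line, 14.9% of 2-fold and 55.2% of 4-fold changes were recovered in iPSC[GSC] against ESC, so many real differences of that size would be missed.

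Alternatives covered the authors' matrix, background correction, scaling, the probe filter, every probe on its own, the treatment of arrays, a replicate block and leaving out each array or, among the GSC-derived clones, each clone (arrays alone for distances). Chosen after seeing the data were the array batches, set by the background level of each array at limits of 86 and 100 (A with 8 arrays, B with 16 including all iPSC[GSC] arrays, C with the 2 MEF arrays), leaving out clones in comparisons with ESC, GSC or iPSC[MEF], and leaving out the lines gPSC[GSCadult] clone 2 and gPSC[GSCneonatal] clone 2. Slide positions are not given in the sources used here.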

Results

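RNA of 13 mouse cell lines was measured on Illumina bead arrays, with 2 arrays per line and 26 arrays in all. Germline stem cells (GSC) are self-renewing spermatogonial stem cells in culture, and 1 line was neonatal (day 10) and 1 adult (day 40). From each of these, 2 clones of induced pluripotent stem cells (iPSC[GSC]) and 2 clones of germline-derived pluripotent stem cells (gPSC, cells that turn pluripotent in GSC cultures without added reprogramming genes) were profiled. The other lines were embryonic stem cells (ESC), embryonic fibroblasts (MEF) and an iPSC line made from fibroblasts and labelled Tet-4F, read here as tetracycline-inducible reprogramming factors (iPSC[MEF]). Every line is labelled with the strain OG2, an Oct4-GFP transgenic mouse. Each array detected between 9984 and 12081 of 25697 probes, and 9840 genes were tested. The number of lines limits the precision of every value. Levels are normalised log2 signals, given as mean ± SD over clones (n = 4, or n = 2 within an origin) or over the 2 arrays of a single line, and differences are log2 fold changes ± SE. A gene detected on no array of one side has only a lower bound for its fold, written as "at least".

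The first comparison asked whether the route out of the germline left a mark, by setting 4 iPSC[GSC] clones against 4 gPSC clones. Pou5f1, which encodes the core pluripotency factor OCT4, stood at 11.83 ± 0.19 in iPSC[GSC] and 11.78 ± 0.22 in gPSC, a difference of 0.06 ± 0.15 (limma adjusted p = 0.916). Nanog, its homeobox partner in the network, stood at 11.76 ± 0.30 and 11.29 ± 0.53 and did not pass either (limma adjusted p = 0.742). Sox2 differed by 0.24 ± 0.28 and Klf4 by 0.58 ± 0.30 (limma adjusted p = 0.795 and 0.742). The genes with the smallest p-values, none of which passed, were Tdgf1, Tma7, Gprc5a, Iapp and Fgfr1op2. Tdgf1, the Nodal co-receptor Cripto and a marker of undifferentiated cells, was 10.13 ± 0.52 in iPSC[GSC] against 7.07 ± 3.18 in gPSC (limma adjusted p = 0.2), because only the neonatal gPSC clones lay at background. Another detected Tdgf1 probe did not follow this one among neonatal clones (−0.41 against 5.46), so these levels may not stand for the whole gene. Gprc5a, an orphan G protein-coupled receptor induced by retinoic acid, was 6.63 ± 0.10 against 5.34 ± 0.61 (limma adjusted p = 0.232), while Iapp, an islet peptide hormone, lay at background in iPSC[GSC], at least 1.36-fold below gPSC (limma adjusted p = 0.254). limma called 0 of 9840 genes, with 491 at an unadjusted p under 0.05, and 0 again on the arrays of batch B alone, with 423.

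Grouped by lists fixed in advance, members of the pluripotency network leaned towards iPSC[GSC] (27 genes, median 0.16), among them Zfp296 (1.03 ± 0.50) and the junction protein gene Jam2 (0.73 ± 0.20). Trophoblast genes leaned the same way (16 genes, median 0.61), with the lineage factor Tead4 at 0.63 ± 0.20 and the simple-epithelium keratins Krt8 (1.63 ± 0.53) and Krt18 (1.79 ± 0.60). So did the 8 two-cell-like genes, which mark a rare totipotent-like state (median 0.64; Tmem92 1.22 ± 0.34, Tcstv1 1.04 ± 0.43), 23 mesoderm and endoderm genes (median 0.37; Lama1 1.51 ± 0.30) and 19 glycolysis genes (median 0.37; Aldoc 1.41 ± 0.91). Fibroblast and matrix genes leaned towards gPSC (37 genes, median −0.59; Mmp2 −1.17 ± 0.56, Zeb1 −0.49 ± 0.15), and so did 21 interferon-response genes (median −0.46; Ifit3 −1.78 ± 1.16). No member of these 7 lists passed over all genes. Adjusted over the list alone, 1 pluripotency gene was higher, and 1 mesoderm and endoderm gene was higher and 1 lower. The set tests passed at the preset correlation, with limma adjusted p = 0.00285, 4.23e-05, 0.00347, 0.0188, 0.00413, 0.000548 and 0.00372 in the order given. None did so with an estimated correlation (limma adjusted p between 0.447 and 0.613). Only the trophoblast call passed without each single clone, and without iPSC[GSCneonatal] clone 1 its median was 0.15 (limma adjusted p = 0.0464), so its size rests largely on that clone. Over single clones left out the other medians ranged from 0.06 to 0.41 (pluripotency), 0.32 to 0.96 (two-cell-like), 0.12 to 0.44 (mesoderm and endoderm), 0.09 to 0.56 (glycolysis), −1.02 to −0.15 (fibroblast) and −0.71 to −0.15 (interferon). Without iPSC[GSCneonatal] clone 1 the fibroblast, mesoderm and endoderm, two-cell-like, interferon and glycolysis calls were lost (limma adjusted p from 0.0557 to 0.103). The pluripotency call was lost without iPSC[GSCneonatal] clone 2 or gPSC[GSCneonatal] clone 2 (limma adjusted p = 0.207 and 0.0677), the mesoderm and endoderm and two-cell-like calls without gPSC[GSCadult] clone 1 (0.539 and 0.194), the interferon and glycolysis calls without gPSC[GSCneonatal] clone 2 (0.307 and 0.136), and the fibroblast, interferon and glycolysis calls without gPSC[GSCadult] clone 2 (1, 0.492 and 0.443). Without gPSC[GSCadult] clone 2 and gPSC[GSCneonatal] clone 2, the medians of the fibroblast, interferon and glycolysis lists were 0.13, 0.14 and −0.11.

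**Figure D1:**
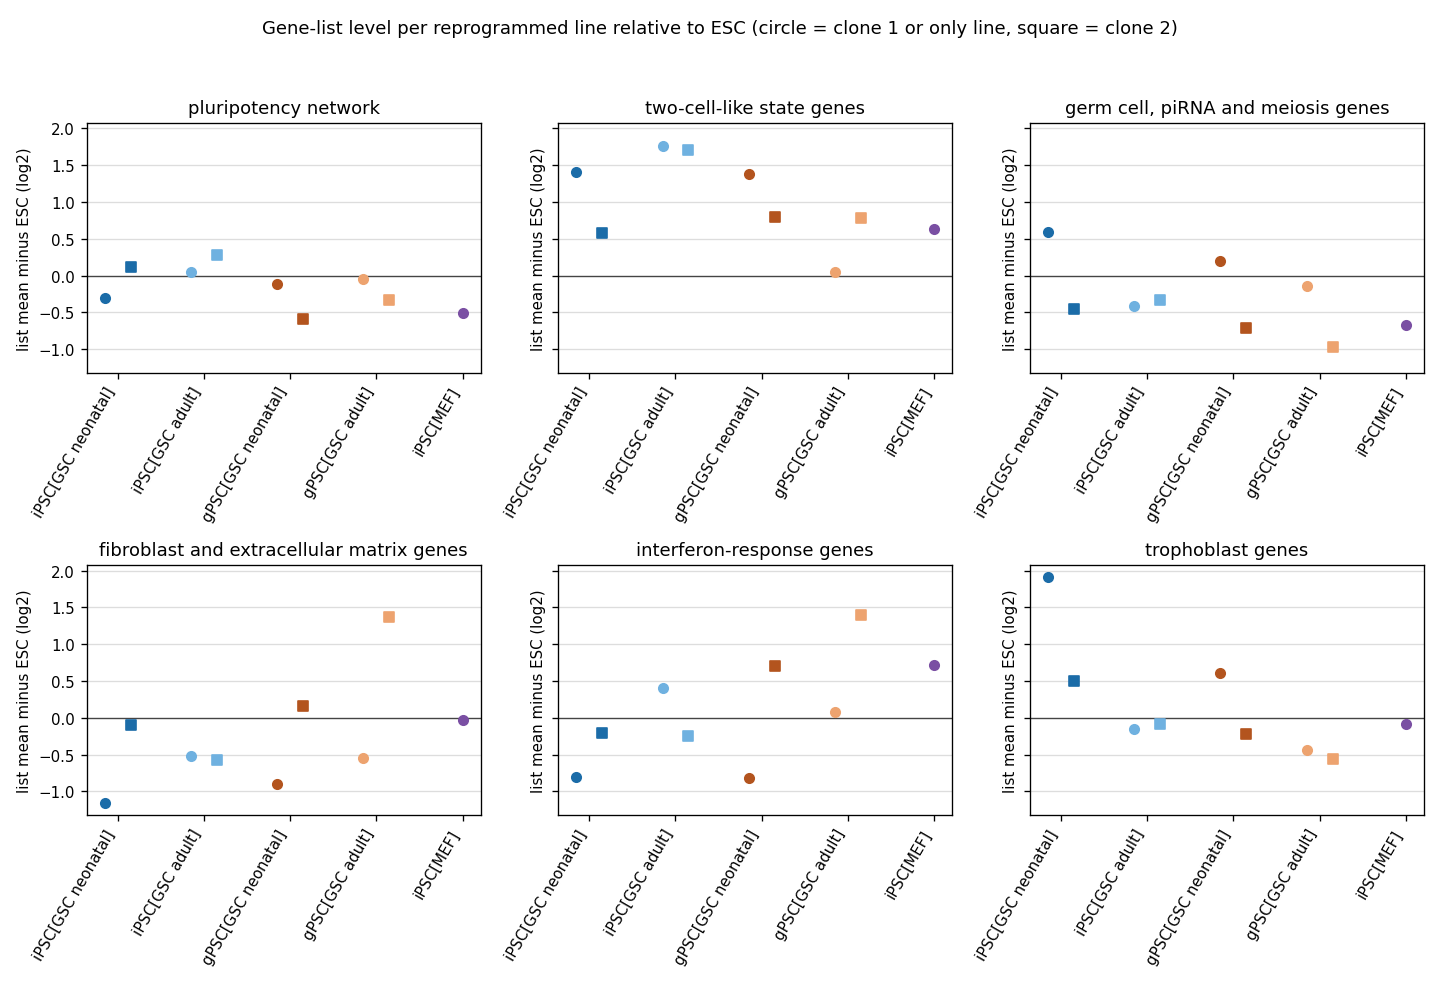
Mean of 6 gene lists in each reprogrammed line minus the mean in ESC (log2; 1 point per line, the mean of 2 arrays; circles are clone 1 or the only line, squares clone 2). The fibroblast list reached 1.37 above ESC in gPSC[GSCadult] clone 2, and the two-cell-like list 1.76 and 1.71 in the iPSC[GSCadult] clones.

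Among clones of neonatal origin (2 against 2), Tdgf1 and Tma7 were the called genes. Tdgf1 was 9.80 ± 0.60 in iPSC[GSC] and at background in gPSC (4.34 ± 0.08), at least 27.5-fold higher (limma adjusted p = 0.0353). Tma7, which encodes a small translation machinery-associated protein, was 6.97 ± 0.10 against 4.61 ± 0.06, at least 3.85-fold higher (limma adjusted p = 0.0331). Both clones of each kind lay on opposite sides for both genes, but another detected Tdgf1 probe differed by −0.41. Tma7 had no other detected probe to check it. By line means, gPSC[GSCneonatal] clone 2 correlated at 0.9973 with iPSC[MEF], where both genes were also at background, and at 0.9489 with clone 1. Whether clone 2 and iPSC[MEF] are cultures of a single line was not tested. If they are, 1 gPSC clone is left in this contrast. Pou5f1, Nanog, Sox2 and Klf4 differed by −0.06 ± 0.22, 0.38 ± 0.42, 0.05 ± 0.40 and 0.44 ± 0.42, and none passed (limma adjusted p from 0.874 to 0.989). Immediate-early and heat shock genes, the first wave of a growth or stress response, leaned towards iPSC[GSC] (23 genes, median 0.26; Dusp1 0.67 ± 0.24, Ier3 1.21 ± 0.46), with limma set test adjusted p = 0.0125 and adjusted p = 0.000532 with an estimated correlation, though 0.0616 at the preset one without iPSC[GSCneonatal] clone 2. Trophoblast genes leaned further that way (median 0.89; Krt18 2.51 ± 0.85), but their limma set test adjusted p = 4.51e-06 became adjusted p = 0.695 with an estimated correlation. Their list mean stood 1.92 above ESC in iPSC[GSCneonatal] clone 1 and 0.50 in clone 2, and without clone 1 the median was 0.15 (limma adjusted p = 0.428). Maternally expressed imprinted genes (18 genes, median 0.24) passed only with the estimated correlation (limma adjusted p = 0.000956, against 0.209). For this set and the immediate-early set the estimate lay below the preset correlation, so the smaller p is not a stricter check. No member of these 3 lists passed, over all genes or adjusted over the list alone, and of the 27 pluripotency genes Tdgf1 passed. limma called 2 genes of 9840, 374 having an unadjusted p under 0.05, and the same 2 on batch B alone. Without background correction it called 0, with 383 under 0.05 unadjusted. Without any 1 of the 4 neonatal clones, which leaves a single clone on a side, limma called 0 (152 to 1281 unadjusted), while Tdgf1 still differed by 5.04 to 5.89 and Tma7 by 2.29 to 2.43.

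Among clones of adult origin (2 against 2), the gene with the smallest p-value was Spint5, a protease inhibitor gene, at 7.93 ± 0.13 in iPSC[GSC] and 5.27 ± 0.09 in gPSC (limma adjusted p = 0.727). Pou5f1, Nanog, Sox2 and Klf4 differed by 0.17 ± 0.22, 0.56 ± 0.42, 0.43 ± 0.40 and 0.73 ± 0.42 (limma adjusted p = 1 for each). Two-cell-like genes leaned towards iPSC[GSC] (8 genes, median 1.42), with Tmem92 at 2.27 ± 0.48 and Zscan4c, the telomere-associated marker of that state, at 10.72 ± 0.07 against 8.44 ± 1.35. The two-cell-like set passed both ways (limma adjusted p = 5.52e-11, and adjusted p = 0.00711 with an estimated correlation), and 5 of its 8 members passed adjusted over the list alone, though 0 over all genes. Its median was 0.91 without gPSC[GSCadult] clone 1 (limma adjusted p = 0.0245) and 1.92 without clone 2. Pluripotency genes (median 0.37; Sall4 0.56 ± 0.18), mesoderm and endoderm genes (median 0.33; Lama1 2.31 ± 0.43) and glycolysis genes (median 0.40; Pgam1 0.41 ± 0.19) leaned towards iPSC[GSC], and fibroblast genes (median −1.03; Mmp2 −1.66 ± 0.80) and interferon genes (median −0.60; Rsad2 −0.79 ± 0.54) towards gPSC. Those 5 sets passed at the preset correlation (limma adjusted p = 0.000447, 4.77e-05, 0.000869, 9.43e-09 and 0.000272) and not with an estimated one (limma adjusted p from 0.0633 to 0.437). Their members did not pass over all genes, and adjusted over the list alone 1 mesoderm and endoderm gene did. Without gPSC[GSCadult] clone 2 the fibroblast, interferon and glycolysis medians were −0.04, 0.01 and −0.13, without gPSC[GSCadult] clone 1 the mesoderm and endoderm median was 0.14 (limma adjusted p = 0.525), and without iPSC[GSCadult] clone 2 the glycolysis call was lost (limma adjusted p = 0.0575) and the pluripotency median was 0.21. limma called 0 genes, with 274 at an unadjusted p under 0.05, and on batch B alone 0, with 241.

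The difference between these contrasts was tested as a method by origin interaction (adult minus neonatal). Tma7 (−2.50 ± 0.22, limma adjusted p = 0.197) and Tdgf1 (−4.80 ± 0.58, limma adjusted p = 0.625) led it without passing. The other Tdgf1 probe did not follow the first in the neonatal contrast. Two-cell-like genes differed with a median of 1.40 (0.82 to 1.95 without single clones), with Zscan4c at 2.84 ± 0.95 (limma set test adjusted p = 2.99e-09, and 0.00711 with an estimated correlation). Immediate-early and heat shock genes had a median of −0.26 (−0.44 to −0.22 without single clones), with Ier3 at −1.96 ± 0.65 (limma adjusted p = 0.00127, and 1.19e-05 with an estimated correlation). Maternally expressed imprinted genes had a median of −0.23 (−0.28 to −0.11 without single clones), with the growth inhibitor Cdkn1c at −2.38 ± 0.77 (limma adjusted p = 0.0193, and 1.13e-05 with an estimated correlation). For the immediate-early and maternally expressed sets the estimate lay below the preset correlation, so the smaller p is not a stricter check. Fibroblast genes (median −0.68), trophoblast genes (−0.68) and mesoderm and endoderm genes (0.26) passed only at the preset correlation (limma adjusted p = 0.00039, 0.0168 and 0.0039, against 0.769, 0.769 and 0.164 estimated). No member of the 6 lists passed over all genes or adjusted over the list alone. Without iPSC[GSCneonatal] clone 1 the trophoblast median was 0.06, and without gPSC[GSCadult] clone 2 the fibroblast median was 0.19. The two-cell-like and immediate-early calls passed without each single clone, while 4 clones each lost the maternally expressed call (limma adjusted p from 0.0775 to 0.317) and the mesoderm and endoderm call (limma adjusted p from 0.182 to 0.518), 5 the trophoblast call (from 0.0794 to 0.427) and 3 the fibroblast call (from 0.241 to 0.35). limma called 0 genes, with 161 at an unadjusted p under 0.05, on all arrays and on batch B alone.

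The age of the source was asked by setting 4 clones of adult origin against 4 of neonatal origin. All clones of an origin came from 1 GSC line, so age cannot be told apart from parent line. Tdgf1 was 10.12 ± 0.59 in adult-derived and 7.07 ± 3.17 in neonatal-derived clones, and Tma7 7.01 ± 0.12 and 5.79 ± 1.36 (limma adjusted p = 0.15 for both), with the neonatal gPSC clones again at background. For Tdgf1 this rests on the probe that the other detected probe did not follow among neonatal clones. Prss8, an epithelial membrane protease, was 6.34 ± 0.40 against 7.28 ± 0.53, and skeletal-muscle actin Acta1 5.30 ± 0.32 against 7.28 ± 0.51 (limma adjusted p = 0.495 and 0.643). Pou5f1 differed by 0.16 ± 0.15, Nanog by −0.20 ± 0.30, Sox2 by 0.02 ± 0.28 and Klf4 by 0.32 ± 0.30, none passing. Trophoblast genes leaned towards neonatal origin (16 genes, median −0.62; Krt8 −2.41 ± 0.53, Krt18 −2.55 ± 0.60, Krt19 −1.79 ± 0.53), as did germ cell genes (26 genes, median −0.43; Tdrd12 −0.52 ± 0.17) and glycolysis genes (median −0.36; Hk1 −0.70 ± 0.37). Interferon genes (median 0.34; Ifi27 2.19 ± 0.70), fibroblast genes (median 0.42; Vim 1.12 ± 0.60) and pluripotency genes (median 0.09; Tbx3 0.54 ± 0.20) leaned towards adult origin. All 6 sets passed at the preset correlation (limma adjusted p = 3.95e-10, 0.04, 0.00609, 0.00132, 0.0185 and 0.0121) and none with an estimated one (limma adjusted p from 0.352 to 0.881). No member passed over all genes. Adjusted over the list alone, 3 trophoblast genes were lower and 1 pluripotency gene higher. Without gPSC[GSCadult] clone 2 the fibroblast median was −0.06, and the germ cell, fibroblast, interferon and glycolysis calls were lost (limma adjusted p from 0.326 to 0.721). The pluripotency call was lost without 4 of the 8 clones: gPSC[GSCneonatal] clone 2, iPSC[GSCneonatal] clone 1, iPSC[GSCadult] clone 2 and gPSC[GSCadult] clone 1 (limma adjusted p = 0.94, 0.076, 0.137 and 0.0875). Without iPSC[GSCneonatal] clone 1 the germ cell and fibroblast medians were −0.10 and 0.21 (limma adjusted p = 0.693 and 0.474), and without gPSC[GSCneonatal] clone 1 −0.12 and 0.17 (limma adjusted p = 0.199 for both, and 0.0724 for glycolysis). The germ cell and fibroblast calls were also lost without iPSC[GSCadult] clone 2 (limma adjusted p = 0.137 for both). Only the trophoblast call passed without each single clone, with a median of −0.41 without iPSC[GSCneonatal] clone 1. limma called 0 genes, with 440 at an unadjusted p under 0.05, and on batch B alone 0, with 479.

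As a comparison of whole profiles, the mean distance (1 minus Pearson r over genes) was 0.0396 between iPSC[GSC] and gPSC clones and 0.0363 within each kind, a difference of 0.00331 (exact one-sided permutation p = 0.257, 9 of 35 splits). By origin it was 0.0395 between and 0.0364 within, a difference of 0.00313 (exact one-sided permutation p = 0.286, 10 of 35 splits). The smallest p this design allows is 0.0286 in an exact test. On batch B alone the differences were 0.00305 and 0.00323. Arrays of a single line correlated at a mean r of 0.9959 across genes (13 pairs), arrays of different clones of one pluripotent type at 0.9607 (16 pairs), and arrays of different pluripotent types at 0.963 (164 pairs). Among these, gPSC[GSCneonatal] clone 2 and iPSC[MEF] correlated at 0.9952 (4 pairs). GSC and pluripotent arrays correlated at 0.8469, and MEF and pluripotent arrays at 0.8023. Genes within an array are not independent replicates.

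**Figure D2:**
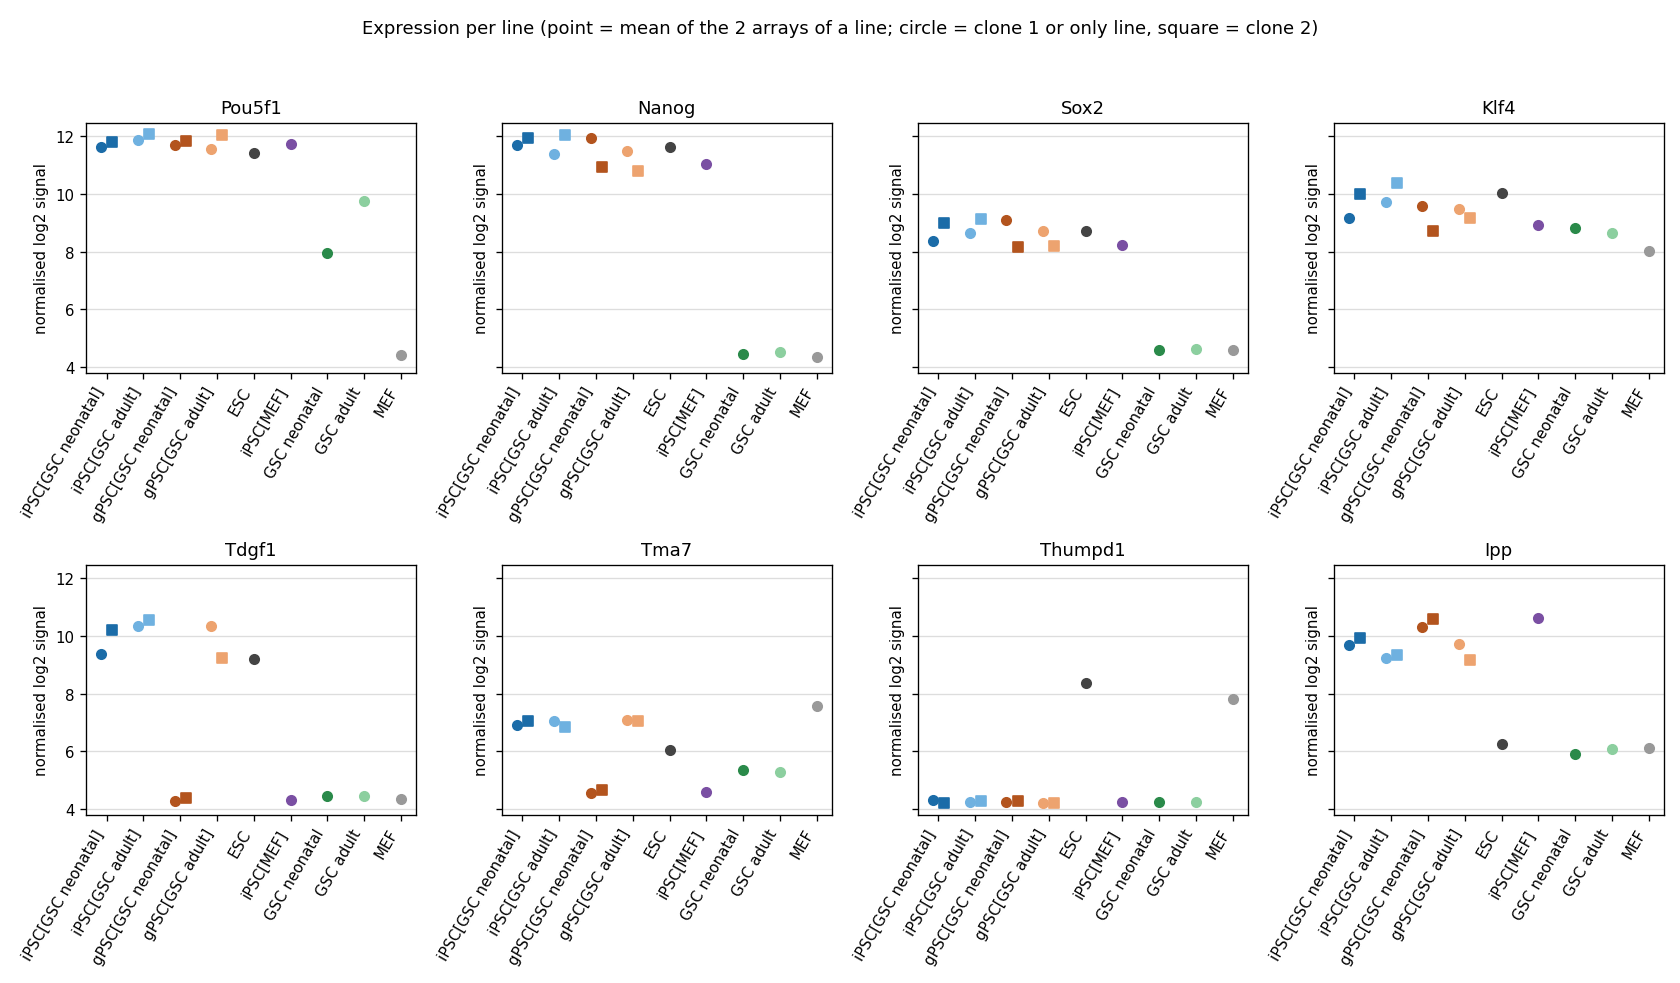
Normalised log2 signal of 8 genes in each of the 13 lines (1 point per line, the mean of 2 arrays; circles are clone 1 or the only line, squares clone 2). Nanog and Sox2 sat at background in GSC and MEF, Tdgf1 at 4.28 and 4.39 in the gPSC[GSCneonatal] clones, and Thumpd1 at 8.36 in ESC.

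Setting the pluripotent clones against the GSC they came from (4 clones against 2 lines) asked what conversion changed. Nanog rose from background, at least 117-fold in iPSC[GSC] (11.76 ± 0.30 against 4.49 ± 0.05, limma adjusted p = 2.03e-16) and at least 84.5-fold in gPSC (11.29 ± 0.53, limma adjusted p = 7.93e-16). Sox2 rose at least 14.8-fold and 12.5-fold, and Pou5f1 from 8.84 ± 1.27 in GSC to 11.83 ± 0.19 and 11.78 ± 0.22 (limma adjusted p = 4.98e-11 and 7.47e-11). Klf4 rose by 1.09 ± 0.29 in iPSC[GSC] (limma adjusted p = 0.00299) and did not pass in gPSC (0.50 ± 0.29, limma adjusted p = 0.159). Wfdc2, an epithelial whey-acidic protein gene, rose at least 117-fold and 74.9-fold, and Dnmt3l, the cofactor of de novo DNA methylation, by 6.81 ± 0.20 and 6.68 ± 0.20 (limma adjusted p = 9.15e-18 and 1.41e-17). Egr4, a zinc-finger factor of spermatogonia, had the largest fall, from 12.85 ± 0.05 to 5.06 ± 0.67 in iPSC[GSC] and 5.65 ± 1.11 in gPSC (limma adjusted p = 6.87e-13 and 2.8e-12). Sohlh1, a germ-cell differentiation factor, fell by 5.90 ± 0.28 and 6.13 ± 0.28, and Mageb4, an X-linked germline gene, by 6.53 ± 0.49 and 6.79 ± 0.49.

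Of 27 pluripotency genes, 26 were higher in iPSC[GSC] and 23 in gPSC (26 and 25 adjusted over the list alone), among them Esrrb (5.41 ± 0.22 and 5.21 ± 0.22) and Gdf3 (at least 24.8-fold and 27.9-fold). Of 23 spermatogonial genes, 17 were lower and 3 higher in both, including the GDNF receptor gene Ret (at least 14.8-fold and 13.2-fold lower) and Neurog3 (at least 7.18-fold and 6.42-fold lower). Of 26 germ cell genes, 21 were lower and 1 higher in both (2 higher in gPSC adjusted over the list alone), such as Tdrkh (−4.77 ± 0.27 and −5.12 ± 0.27), Tex11 (−4.02 ± 0.29 and −4.12 ± 0.29) and Piwil4 (limma set test adjusted p = 1.2e-09 and 5.67e-12, but 0.0907 and 0.0596 with an estimated correlation). DNA methylation enzymes were higher in 8 and lower in 2 of 14 in iPSC[GSC] (9 and 2 adjusted over the list alone), and 9 and 2 in gPSC, with Dppa3 up by 3.29 ± 0.21 and 3.02 ± 0.21. Glycolysis genes were higher in 17 and 15 of 19 (Ldha 3.21 ± 0.18 and 3.01 ± 0.18, Hk2 3.24 ± 0.25 and 2.95 ± 0.25), with limma set test adjusted p = 6.61e-10 and 1.34e-07, but 0.0907 and 0.166 with an estimated correlation. p53 targets were higher in 11 and 12 of 20, with 1 lower in each (Bbc3 3.60 ± 0.20 and 3.80 ± 0.20, Cdkn1a 2.23 ± 0.17 and 2.34 ± 0.17). Primed epiblast genes were higher in 7 and lower in 1 of 15 in iPSC[GSC], and higher in 11 in gPSC (Otx2 at least 28.8-fold and 27.1-fold; set median in gPSC 1.79, and 1.10 without gPSC[GSCneonatal] clone 2). Two-cell-like genes were higher in 6 of 8 in iPSC[GSC], and in gPSC 5 were higher and 1 lower (Zscan4c at 9.89 ± 1.08 and 9.04 ± 1.06 against background). Trophoblast genes passed as a set in iPSC[GSC] (10 of 16 higher, 1 lower; Krt8 4.31 ± 0.45) at limma adjusted p = 0.00859, but at 0.568 with an estimated correlation, 0.0584 with 1 mean per line and 0.0575 without iPSC[GSCneonatal] clone 1. Fibroblast genes passed in gPSC (11 of 37 higher, 9 adjusted over the list alone; Ccn2 3.59 ± 0.17) at limma adjusted p = 0.026, but at adjusted p = 0.764 with an estimated correlation and 0.0876 with 1 mean per line. The fibroblast list mean was 8.55 in gPSC[GSCadult] clone 2 and 6.28, 7.34 and 6.63 in the other gPSC clones, and the median of 0.54 was 0.10 without it (limma adjusted p = 0.337) and 0.25 without gPSC[GSCneonatal] clone 2 (limma adjusted p = 0.131). Of the 4 reprogramming factors, Pou5f1, Sox2 and Klf4 were higher in iPSC[GSC], Pou5f1 and Sox2 in gPSC, and Myc was detected on no array of either side.

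At the preset correlation, limma set test adjusted p was 3.2e-37 and 7.43e-34 for pluripotency genes, and 2.91e-13 and 3e-13 for spermatogonial genes. The pluripotency, spermatogonial, DNA methylation, primed epiblast, p53 and reprogramming factor sets also passed with an estimated correlation in both contrasts, and the two-cell-like set in iPSC[GSC] (limma adjusted p = 0.0442, against 0.132 in gPSC). limma called 4721 genes between iPSC[GSC] and GSC (2200 higher, 2521 lower, 2605 at least 2-fold) and 4602 between gPSC and GSC (2082 higher, 2520 lower, 2504 at least 2-fold). With 1 mean per line it called 3986 and 3728, of which 3743 and 3523 were among them. Batch B alone gave 3841 and 3649, and batch A alone 2042 for gPSC, with no iPSC[GSC] array in batch A.

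Fibroblast reprogramming served as the reference conversion (iPSC[MEF] against MEF, 2 arrays each). Pou5f1 rose at least 83.9-fold (11.72 ± 0.12 against 4.40 ± 0.26, limma adjusted p = 1.53e-13), Nanog at least 52.0-fold and Sox2 at least 7.32-fold, while Klf4 differed by 0.89 ± 0.47 (limma adjusted p = 0.159). Dppa5a, an RNA-binding pluripotency gene, had the largest rise, at least 303-fold (limma adjusted p = 3.78e-15). Actg2, the smooth-muscle gamma actin, fell at least 103-fold, and the alpha actin Acta2 fell by 5.86 ± 0.57 (limma adjusted p = 4.83e-08). The Y-linked Eif2s3y was 8.96 ± 0.10 in MEF and at background in iPSC[MEF], at least 15.3-fold lower (limma adjusted p = 2.22e-06). Of 37 fibroblast genes 30 were lower and 1 higher (32 and 2 adjusted over the list alone; Thbs1 −5.13 ± 0.57, Tagln at least 25.6-fold lower), and of 27 pluripotency genes 24 were higher (Dppa4 at least 84.8-fold). DNA methylation enzymes were higher in 9 and lower in 1 of 14 (10 and 1 adjusted over the list alone; Dnmt3b 6.77 ± 0.67), and primed epiblast genes higher in 12 of 15 (Otx2 at least 15.9-fold). Neural and ectoderm genes were lower in 7 of 14 (8 adjusted over the list alone; Nes −2.66 ± 0.37, Meis1 −2.95 ± 0.46). Germ cell genes were higher in 8 and lower in 1 of 26 (10 and 1 adjusted over the list alone; Tex19.1 at least 32.7-fold), two-cell-like genes higher in 4 of 8 (Zscan4c at least 12.2-fold) and glycolysis genes higher in 7 of 19 (Slc2a3 5.69 ± 0.47). Among the reprogramming factors Pou5f1 and Sox2 were higher and Myc lower (at least 2.43-fold).

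The limma set test adjusted p was 3.78e-54 for pluripotency genes, 2.22e-08 for DNA methylation enzymes, 6.74e-09 for primed epiblast genes, 0.000681 for neural genes and 0.000417 for reprogramming factors, and these 5 passed with an estimated correlation. Fibroblast genes went from limma adjusted p = 2.16e-17 to adjusted p = 0.13 with an estimated correlation, and the germ cell, two-cell-like and glycolysis sets to 0.395, 0.378 and 0.589. With 1 mean per line the two-cell-like and glycolysis sets had limma adjusted p = 0.147 each. limma called 3136 genes (1655 higher, 1481 lower), and 1823 with 1 mean per line, 1723 of them shared. Under median scaling all genes shifted by a median of −0.39 and the calls split into 992 higher and 3311 lower, and Ndufv1, called at 0.94 ± 0.31 (limma adjusted p = 0.0208), stood at −0.07. The MEF arrays formed an array batch of their own, set by background level after the data were seen, so batch and cell type cannot be told apart in this contrast. Between batches A and B the arrays of a line differed at least 2-fold in at most 10 genes, against 2813 genes called and at least 2-fold apart here. That sets no bound for the MEF batch. The 95th percentile of its signal was 26.24 and 24.88 times background, against at most 11.25 on the other arrays.

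Against ESC, the question was how far each pluripotent type departed from the embryonic reference (4 clones or 1 line against 1 ESC line). Pou5f1 was 11.42 ± 0.12 in ESC and differed by 0.41 ± 0.27 in iPSC[GSC], 0.36 ± 0.27 in gPSC and 0.31 ± 0.35 in iPSC[MEF], and Nanog by 0.14 ± 0.33, −0.33 ± 0.33 and −0.59 ± 0.41, none passing. Sox2 differed by 0.07 ± 0.36, −0.17 ± 0.36 and −0.50 ± 0.45, and Klf4 by −0.22 ± 0.37, −0.81 ± 0.37 and −1.11 ± 0.47 (limma adjusted p from 0.628 to 1). Thumpd1, an RNA acetylation adaptor gene, was 8.36 ± 0.02 in ESC and at background in every clone and in iPSC[MEF], at least 11.2-fold, 10.0-fold and 10.1-fold lower (limma adjusted p = 6.24e-12, 5.61e-12 and 8.99e-10). Trim59, a ubiquitin ligase gene, was at least 9.11-fold, 8.14-fold and 8.23-fold lower. Of the other lines only MEF gave signal for them (7.82 and 7.41). Ipp, an actin-binding Kelch protein gene, was higher by 3.29 ± 0.27, 3.68 ± 0.27 and 4.34 ± 0.34 (limma adjusted p = 5.79e-08, 5.8e-09 and 2.4e-08), and Twistnb, now known as an RNA polymerase I subunit gene, by 2.49 ± 0.29, 2.66 ± 0.29 and 3.03 ± 0.37. The smooth-muscle LIM gene Csrp1 was lower by −2.61 ± 0.29, −2.94 ± 0.29 and −2.72 ± 0.36.

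iPSC[GSC] clones had 4 of 8 two-cell-like genes above ESC (5 adjusted over the list alone): Tcstv1 (2.47 ± 0.49), Tmem92 (2.30 ± 0.36), Zscan4c (2.13 ± 0.45) and Tcstv3 (1.96 ± 0.45), with limma set test adjusted p = 4.78e-15 and adjusted p = 0.00023 with an estimated correlation. Grb10, a maternally expressed imprinted growth inhibitor, was 6.52 ± 0.38 against 9.01 ± 0.03 (limma adjusted p = 0.00149), 1 of 18 maternally expressed genes lower (2 adjusted over the list alone; set test limma adjusted p = 0.0314, and 0.000451 estimated). Egr4 and Neurog3 were lower among 23 spermatogonial genes (−2.41 ± 0.56, and at least 1.27-fold; set test limma adjusted p = 0.00627, and 0.0128 estimated), and Acta2 was lower by −2.00 ± 0.45 among 37 fibroblast genes. In gPSC, Zfp42, the pluripotency marker Rex1, was lower by −1.60 ± 0.37 (limma adjusted p = 0.048), the sterol gene Msmo1 by −2.47 ± 0.45 and the imprinted Phlda2 by −1.76 ± 0.36. Tdgf1 passed as well (−2.14 ± 0.41, limma adjusted p = 0.0128) but at background in the neonatal clones alone, and another Tdgf1 probe gave −0.64. In gPSC 1 of 18 maternally expressed genes was lower (4 adjusted over the list alone; set test limma adjusted p = 0.0158, and 2.49e-05 estimated), and immediate-early genes were lower as a set with 0 of 23 passing (median −0.35; limma adjusted p = 0.0308, and 0.00397 estimated). In iPSC[MEF], Tdgf1 was at least 18.2-fold lower (limma adjusted p = 5.64e-06; another probe −0.54), Eif2s3y at least 10.0-fold and Erdr1, a secreted apoptosis regulator of the pseudoautosomal region, at least 19.3-fold. The immediate-early set was again lower (median −0.30, 0 of 23 passing, limma adjusted p = 0.00806, and 0.0011 estimated). Where p fell for the maternally expressed and immediate-early sets, the estimate lay below the preset correlation and is not a stricter check.

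Sets that passed against ESC only at the preset correlation were, in iPSC[GSC], fibroblast genes (median −0.43), paternally expressed imprinted genes (−0.14, and −0.27 to −0.02 without single clones) and trophoblast genes (0.48), with 2 paternally expressed genes lower adjusted over the list alone, at limma adjusted p = 0.657, 0.158 and 0.538 estimated. In gPSC they were germ cell genes (−0.49), two-cell-like genes (0.72; 3 higher adjusted over the list alone) and glycolysis genes (−0.40), at limma adjusted p = 0.677, 0.134 and 0.712 estimated, with germ cell and glycolysis medians of −0.04 and 0.16 without gPSC[GSCadult] clone 2 and gPSC[GSCneonatal] clone 2. In iPSC[MEF] they were pluripotency (−0.36; Tdgf1 and 0 other members passing, 3 lower adjusted over the list alone), germ cell, paternally imprinted, primed epiblast, two-cell-like, sex-linked, interferon and glycolysis genes, at limma adjusted p from 0.0798 to 0.525 estimated. With 1 mean per line more sets were lost: both imprinted sets in iPSC[GSC] (limma adjusted p = 0.258 each), the germ cell, maternally expressed, glycolysis and immediate-early sets in gPSC (limma adjusted p from 0.212 to 0.297) and every set in iPSC[MEF] (limma adjusted p from 0.0856 to 0.27). Single clones lost calls too. In iPSC[GSC] the trophoblast median was 0.12 without iPSC[GSCneonatal] clone 1 (limma adjusted p = 0.0736), where the fibroblast and spermatogonial medians were −0.26 and −0.09, and the paternally expressed call was lost without iPSC[GSCneonatal] clone 2 or iPSC[GSCadult] clone 2 (0.326 and 0.127) and the maternally expressed one without iPSC[GSCneonatal] clone 2 or iPSC[GSCadult] clone 1 (0.097 and 0.076). In gPSC the germ cell and glycolysis calls were lost without gPSC[GSCneonatal] clone 2 (limma adjusted p = 0.22 and 0.54) or gPSC[GSCadult] clone 2 (0.217 and 0.732), and the immediate-early call without gPSC[GSCadult] clone 1 (0.0621). limma called 72 genes for iPSC[GSC] (28 higher, 44 lower), 58 for gPSC (17 and 41) and 16 for iPSC[MEF] (4 and 12). Single units moved these counts: for iPSC[GSC] to 29 without iPSC[GSCneonatal] clone 1, 33 without iPSC[GSCadult] clone 2 and 47 and 45 without ESC arrays 1 and 2, for gPSC to 207 without gPSC[GSCadult] clone 1, and for iPSC[MEF] to 10 without iPSC[MEF] array 2. With 1 mean per line it called 6, 6 and 3, all among them: Ipp, Thumpd1 and Trim59 in each, with Csrp1 in iPSC[GSC] and gPSC. In the authors' normalised values the iPSC[GSC] calls split into 16 higher and 10 lower, and the gPSC calls into 9 and 11. Batch B alone gave 4, 5 and 4 calls, and batch A alone 0 for gPSC and iPSC[MEF], with 263 and 170 at an unadjusted p under 0.05 by limma.

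Induced pluripotent cells of different source were compared as iPSC[GSC] (4 clones) against iPSC[MEF] (1 line), so source and line cannot be told apart. Pou5f1 differed by 0.11 ± 0.27, Nanog by 0.72 ± 0.33, Sox2 by 0.57 ± 0.36 and Klf4 by 0.89 ± 0.37, none passing (limma adjusted p from 0.389 to 0.957). Tdgf1 was at least 34.4-fold higher in iPSC[GSC] (10.13 ± 0.52 against 4.32 ± 0.06, limma adjusted p = 7.19e-09), but another Tdgf1 probe differed by −0.08. Eif2s3y was at least 11.9-fold, Erdr1 4.94-fold and Tma7 3.82-fold higher (limma adjusted p = 1.51e-05, 8.06e-05 and 0.0191). Grb10 was lower by −2.25 ± 0.39 (limma adjusted p = 0.0155) and Clca3b, a secreted metalloprotease gene, by −1.58 ± 0.31 (limma adjusted p = 0.0385). Primed epiblast genes were lower as a set (15 genes, median −1.29; Fgf8 −2.59 ± 0.68, Fgf5 −2.29 ± 0.61, Dnmt3b −1.80 ± 0.53), with 0 members passing over all genes and 7 lower and 1 higher adjusted over the list alone (limma adjusted p = 6.11e-06, and 0.0372 estimated). The sex-linked set, in which Eif2s3y passed, had limma adjusted p = 0.0136 and 0.0347 estimated, but 0.113 with 1 mean per line and 0.054 without iPSC[GSCadult] clone 1, and immediate-early genes passed only with an estimated correlation (limma adjusted p = 0.0372). Pluripotency (median 0.40; Fgf4 1.43 ± 0.46), germ cell (0.51), fibroblast (−0.33; Dcn −2.54 ± 0.91), mesoderm and endoderm (0.30), trophoblast (0.42), two-cell-like (0.78), interferon (−0.80; Oasl2 −2.73 ± 0.95) and glycolysis sets (0.48) passed only at the preset correlation (limma adjusted p from 0.0892 to 0.597 estimated). The germ cell, fibroblast and mesoderm and endoderm sets were also lost with 1 mean per line (limma adjusted p = 0.113 each), and the germ cell, fibroblast and trophoblast sets without iPSC[GSCneonatal] clone 1 (medians 0.19, −0.19 and 0.27; limma adjusted p = 0.156, 0.223 and 0.119), where the mesoderm and endoderm median was 0.08 (limma adjusted p = 0.0312). Of these members Tdgf1 passed over all genes, and adjusted over the list alone 4 mesoderm and endoderm genes were higher and 1 lower, and 2 trophoblast and 3 two-cell-like genes higher. limma called 12 genes (9 higher, 3 lower), 32 without iPSC[GSCadult] clone 1 and 3 without iPSC[GSCadult] clone 2, and 2 with 1 mean per line, Tdgf1 and Tma7, and in the authors' normalised values 6 higher and 1 lower. On batch B alone it called 0, with 253 at an unadjusted p under 0.05.

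A memory of the source cell was sought across genes, by setting the iPSC[GSC] minus iPSC[MEF] difference beside the GSC minus MEF difference. Pearson r was 0.108 and Spearman rho 0.083 over 9840 genes, which are not independent replicates. With batch B arrays alone for every line but MEF, r was 0.113. The MEF arrays are all in batch C, so this does not remove their batch. Over the 3661 genes called and at least 2-fold apart between GSC and MEF r was 0.166, and with genes detected on all arrays 0.05. Single clones gave r of 0.091, 0.040, 0.166 and 0.117 (0.103 ± 0.052, SD, n = 4). Set against iPSC[MEF] in the same way, the ESC line, which came from neither source, gave 0.063 and the gPSC clones 0.136, −0.114, 0.237 and −0.39.

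Each age is represented by 1 GSC line with 2 arrays, so age and line are the same contrast, and the spread between lines comes from the other cell types. No p-value here can support a difference between adult and neonatal cells beyond these lines. Between them, Neurog3, a transcription factor of spermatogonia entering differentiation, was 8.43 ± 0.03 in the adult and 7.01 ± 0.01 in the neonatal line (limma adjusted p = 0.0139). Pou5f1 was 9.74 ± 0.16 against 7.94 ± 0.02 (limma adjusted p = 0.138), Klf4 differed by −0.15 ± 0.47, and Nanog and Sox2 were at background in both. p53 targets (20 genes, median −0.23; Zmat3 −0.84 ± 0.36, Cdkn1a −0.63 ± 0.28) and immediate-early genes (23 genes, median −0.34; Atf3 −0.92 ± 0.35) were lower in the adult line, with limma set test adjusted p = 2.72e-06 and 5.51e-06, and 0.0187 and 5.68e-10 estimated. They were limma adjusted p = 0.000203 and 0.0034 with 1 mean per line, which sets 1 sample against 1. The 4 reprogramming factors had a median of 0.02 and a mean of 0.42 (limma adjusted p = 0.000184, 0.000873 estimated and 0.000203 with 1 mean per line), with Pou5f1 passing adjusted over the list alone. Fibroblast genes (median −0.26; Vim −1.04 ± 0.69) were lower only at the preset correlation (limma adjusted p = 0.000587, 0.904 estimated and 0.119 with 1 mean per line). No other member of these lists passed, over all genes or adjusted over the list alone. limma called 1 gene, and 0 with 1 mean per line, with 44 at an unadjusted p under 0.05. Batches B and A alone gave 0 calls by limma, with 61 and 16 under 0.05 unadjusted.

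Testis somatic cell genes (9 measured) and oxidative phosphorylation genes (32 measured) passed the set test in none of the 13 comparisons. Adjusted over the list alone, 3 testis somatic genes were lower in iPSC[MEF] against MEF, and 6 oxidative phosphorylation genes in iPSC[GSC] against GSC. Members of the first did pass against GSC, with 4 higher and 2 lower in both iPSC[GSC] and gPSC, including the homeobox gene Rhox5 (6.90 ± 0.36 and 5.97 ± 0.36) and Wt1 (−4.07 ± 0.34 and −3.47 ± 0.34). Of the oxidative phosphorylation genes 7 were higher and 7 lower in iPSC[GSC] against GSC, such as Uqcrc2 (0.78 ± 0.17) and Cox4i1 (−0.96 ± 0.19), and 6 and 7 in gPSC. In iPSC[MEF] against MEF 3 testis somatic genes were higher and 2 lower (Inhba −5.10 ± 0.70), and 2 oxidative phosphorylation genes were higher and 2 lower (Cyc1 1.03 ± 0.30).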

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

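The two-cell-like, imprinted and immediate-early differences below come from tests fixed in advance, the single-array and mixture tests were chosen after their results were seen, and the fibroblast and split tests were chosen after the list levels or calls had been seen but before their own results. Among 42 groups of 4 clones, 3 had a clone far from the other 3, and chance flags about 1 in 20 groups. Germ cell genes in iPSC[GSCneonatal] clone 1 averaged 0.60 above ESC (log2), against −0.46, −0.42 and −0.33 in the other iPSC[GSC] clones. DNA methylation enzymes in gPSC[GSCneonatal] clone 2 averaged 0.13 above ESC, against 0.06, 0.06 and 0.04 in the other gPSC clones, and immediate-early and heat shock genes −0.40, against −0.27, −0.28 and −0.27. The difference between iPSC[GSC] and gPSC differed between adult and neonatal origin for two-cell-like genes (median difference 1.40), maternally expressed imprinted genes (−0.23) and immediate-early and heat shock genes (−0.26), by set tests of the interaction in limma. No member of these lists passed, and set tests do not measure the spread of list means between clones. Two-cell-like means above ESC for clones 1 and 2 were 1.41 and 0.58 (iPSC[GSCneonatal]) and 1.38 and 0.79 (gPSC[GSCneonatal]). At adult origin they were 1.76 and 1.71 (iPSC[GSCadult]) and 0.05 and 0.78 (gPSC[GSCadult]). For the imprinted and immediate-early lists the estimated correlation lay below the preset one, so passing with it is not a stricter check. The imprinted difference was lost without iPSC[GSCadult] clone 1, gPSC[GSCneonatal] clone 1 or either gPSC[GSCadult] clone (limma adjusted p from 0.0775 to 0.317).

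The means of the fibroblast and interferon lists were higher in gPSC[GSCadult] clone 2 than in every other clone, with 5 of 37 and 4 of 21 members going otherwise, among them Ccn2 (11.45 against up to 12.47), Acta2 (9.05 against up to 9.20) and Tagln (4.42 against up to 4.69). Both of its arrays showed this (2 of 2; fibroblast list 8.56 and 8.54 against at most 7.34 elsewhere, interferon list 8.18 and 8.12 against at most 7.47), which excludes a single aberrant array. Of 174 genes at least 8-fold higher in MEF than in iPSC[MEF], 88.5% lay above their mean in the other gPSC clones, at a median 8.52% of the MEF level. The share was 33.3% to 73% for iPSC[GSC] clones against each other. For the other gPSC clones it was 8% to 52.9%. Their reference means hold gPSC[GSCadult] clone 2, which pushes these shares down by construction, so they are no fair contrast to 88.5%. Fibroblasts, such as feeder cells, in the culture of gPSC[GSCadult] clone 2 would give a high share. Fibroblast list members were not removed, however, so choosing this clone by that list set part of the share. The most abundant genes of the list, written before, were Bgn, Dcn and Ccn2 (12.49, 11.68 and 11.45). Ccn2 averaged 11.88 in the other 7 clones, and ESC too expressed 28 of the list's 37 genes on both arrays. A mixture would join cells like the MEF profiled here with cells like the other clones. Against it as the whole cause, 6 of 58 genes stood at least 1 (log2) above both, such as Lum (11.21 against 5.21 in MEF and at most 9.13 in other clones) and Ifit3 (10.12 against 4.88 and at most 7.78). The MEF arrays form a batch of their own with higher signal over background. No such count was made for the other clones either, so these values do not exclude a mixture. For the interferon list as a set the values also argue against it, though 4 of 21 members were not highest in this clone. That list's mean was 6.17 in MEF, 8.15 in this clone and at most 7.46 in the other clones. For the other fibroblast genes such a mixture remains open, although 5 of 37 were not highest in this clone, among them Acta2 and Tagln (13.98 and 9.70 in MEF). Fibroblasts in another state and differentiation within the culture also remain open, the latter not tested.

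The grouping of clones by method was set against all 35 splits of the 8 clones into groups of 4, with no other term in the fit. For the 0 calls this decides nothing, since no split can call fewer (35 of 35 by method and 35 of 35 by origin; highest other split 1638). At an unadjusted p under 0.05, 12 of 35 splits had as many genes as the 553 by method and 13 of 35 as many as the 487 by origin, the highest other having 3410. A random grouping of the clones could therefore give these unadjusted counts. The highest split set iPSC[GSCneonatal] clones 1 and 2, iPSC[GSCadult] clone 2 and gPSC[GSCneonatal] clone 1 against the rest, which include gPSC[GSCadult] clone 2. That points to a structure of the samples, picked as the highest of the splits, and the cause was not tested. Against GSC, 15 splits cannot give a share under 0.05: the real split was the only 1 of 15 to call as many for iPSC[GSC] (4848; highest other 0) and the only 1 of 15 for gPSC (4105; highest other 1).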

How the results depend on the processing

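Batches, doubted lines and clones left out against ESC, GSC or iPSC[MEF] were chosen after the results were seen; all other settings before. Signal over background limits genes near background, and 1 line per side limits ESC, MEF and iPSC[MEF]. The 0 calls by limma between iPSC[GSC] and gPSC, in adult clones, in the interaction and by origin stayed 0 under every scaling and filter and without any array or clone; distances, for which no clone was left out, kept p between 0.2 and 0.286 (exact test). Treating arrays as replicates moved them, by construction. Below, counts are limma calls, the order for ESC is iPSC[GSC], gPSC, iPSC[MEF], and the cause of a change was not tested unless the construction shows it.

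In the authors' matrix the GSC lines gave 0 calls (47 unadjusted), ESC 26, 20 and 9, and iPSC[GSC] against iPSC[MEF] 7. Without detection p in the background step neonatal clones gave 0 (377 unadjusted) and the GSC lines 3. With no background correction they gave 0 (383) and 3, and iPSC[MEF] against ESC 29. Median scaling gave 1 and 0 (56), and Ndufv1 reversed in iPSC[MEF] against MEF (−0.07). With no filter neonatal clones gave 1, the GSC lines 10, ESC 207, 282 and 112, and iPSC[GSC] against iPSC[MEF] 36. With genes detected on all arrays (fewer tested) neonatal clones gave 0 (190) and the GSC lines 0 (16), iPSC[GSC] and gPSC against GSC 2868 and 2790, iPSC[MEF] against MEF 1765, ESC 10, 19 and 2, and iPSC[GSC] against iPSC[MEF] 1. Sex-linked medians, with 3 genes left, were −0.02 (iPSC[MEF] against ESC) and −0.22 (iPSC[GSC] against iPSC[MEF]), and their set tests turned. Every probe on its own gave 2 for the GSC lines and 7 for iPSC[GSC] against iPSC[MEF].

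For all clones, neonatal, adult, interaction and origin, clone as random block gave 8, 7, 9, 4 and 11 calls, and independent arrays 484, 290, 167, 65 and 494. Independent arrays gave 33 for the GSC lines, 5511 for iPSC[MEF] against MEF, ESC 672, 835 and 611, and iPSC[GSC] against iPSC[MEF] 926. Line means gave 0 (44 unadjusted) for the GSC lines, 1823 for iPSC[MEF] against MEF, ESC 6, 6 and 3, and iPSC[GSC] against iPSC[MEF] 2 (on simulated data 52.3% to 60.5% of random-block calls were unchanged genes). The simulated share came from data with few changed genes and need not hold for pluripotent cells against GSC or MEF. A replicate block (array number as a paired term) gave 7, 8, 9, 4 and 9 for the clone comparisons, 1 for the GSC lines, 4703, 4571 and 3098 against GSC and MEF, ESC 63, 55 and 15, and iPSC[GSC] against iPSC[MEF] 9. Not every pair of lines deviates together by number, since 28 of 78 had r over 0.1 (−0.188 to 0.41). In the 8 lines with array 1 in batch A and array 2 in batch B the number marks the batch, and their 28 pairs had a median r of 0.242 (lowest 0.083), against −0.0185 in the others. Batch as a term gave 6, 7, 9, 5 and 11, and 7 for iPSC[GSC] against iPSC[MEF]. Batch B alone gave 0 for the GSC lines (61 unadjusted), ESC 4, 5 and 4, and iPSC[GSC] against iPSC[MEF] 0 (253). Batch A alone gave 0 for the GSC lines (16), 2042 for gPSC against GSC, and 0 for gPSC and iPSC[MEF] against ESC (263 and 170). A block by slide was not run, as the files give no slide.

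Leaving out single arrays or clones gave ranges of 0 to 0 calls for all clones, adult, interaction and origin, 0 to 3 for neonatal clones, 1 to 2 for the GSC lines, 4254 to 4737, 4227 to 4622 and 2990 to 3199 against GSC and MEF, ESC 29 to 103, 44 to 207 and 10 to 20, and 3 to 32 for iPSC[GSC] against iPSC[MEF]. Distances, left out by array alone, ranged over 0.00317 to 0.00345 (methods) and 0.00306 to 0.00321 (origins), and the source-cell r, by array or clone, over 0.09 to 0.118; it was 0.166 over 3661 genes and 0.05 with genes detected on all arrays. Neonatal calls were 0 without any of the 4 neonatal clones (152 to 1281 unadjusted; 1 clone left on a side, Tdgf1 still 5.04 to 5.89) or iPSC[GSCadult] clone 1 array 2 (359), 1 without gPSC[GSCadult] clone 2 array 2 and 3 without gPSC[GSCneonatal] clone 1 array 2. The GSC lines gave 2 without either MEF array. iPSC[GSC] against ESC gave 47 and 45 without ESC arrays 1 and 2, 29 without iPSC[GSCneonatal] clone 1 and 33 without iPSC[GSCadult] clone 2. gPSC against ESC gave 207 without gPSC[GSCadult] clone 1, and iPSC[MEF] against ESC 10 without iPSC[MEF] array 2. iPSC[GSC] against iPSC[MEF] gave 32 without iPSC[GSCadult] clone 1, 3 without its clone 2, 6 without iPSC[GSCneonatal] clone 2 array 1 or 2, iPSC[GSCadult] clone 1 array 1 or clone 2 array 2, gPSC[GSCneonatal] clone 2 array 2 or iPSC[MEF] array 2, and 7 without iPSC[GSCadult] clone 2 array 1, gPSC[GSCneonatal] clone 1 array 2 or clone 2 array 1, or iPSC[MEF] array 1.

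Set tests turned direction without gPSC[GSCadult] clone 2, with medians of fibroblast −0.04 (sign kept), interferon 0.01 and glycolysis −0.13 in adult clones (−1.87, −1.05 and 0.89 without clone 1, the other ends of the ranges), fibroblast 0.19 in the interaction (−1.79) and −0.06 by origin (0.82). The trophoblast interaction was 0.06 without iPSC[GSCneonatal] clone 1 and −1.36 without its clone 2. Without the 2 doubted gPSC lines fibroblast was 0.13, interferon 0.14 and glycolysis −0.11 between iPSC[GSC] and gPSC, germ cell −0.04 and glycolysis 0.16 in gPSC against ESC, and gPSC against ESC gave 38 calls. Of list results with an estimated correlation, 202 stayed, 56 became weaker and 2 stronger; of named genes with line means, 407 stayed and 83 became weaker.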

Other observations

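The tests of other probes, of neighbouring genes and of the line pair were chosen after the result was seen, and the genes named here outside the naming rule were chosen after their values were seen. Thumpd1, Trim59 and Abhd16a were detected in ESC (8.36, 8.06 and 6.78) and in MEF (7.82, 7.41 and 7.51) and lay at background in iPSC[MEF], both GSC lines and all 8 clones. From MEF to iPSC[MEF] they fell at least 6.97-fold, 5.22-fold and 5.60-fold (limma adjusted p = 4.36e-10, 0.0012 and 2.4e-05). Tdgf1 was at background in both gPSC[GSCneonatal] clones (4.28 and 4.39) and in iPSC[MEF] (4.32), and so was Tma7 (4.57, 4.65 and 4.60).

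Genes called against ESC, between iPSC[GSC] and iPSC[MEF], or in the neonatal comparison could differ through sequence variants under single probes, although the labels give strain OG2 for every line, if that stock was not fully inbred, which was not tested. For 17 of the 98 genes another probe was detected, and its change was a median 0.558 of the first probe's, against 0.77 for genes called against GSC. That argues against variants as the whole cause among these 17 genes, though 10 of 42 ratios lay under 0.25. The ratios repeat genes over probes and comparisons, so they are not independent. Thumpd1, Trim59, Ipp, Csrp1 and Tma7 had no other detected probe, so variants remain open for them. For Tdgf1 in the neonatal comparison the ratio was −0.076 (5.46 and −0.41), which is consistent with a variant or a transcript form seen by 1 probe only, and that call should not be read as a change of the whole gene. Stretches of chromosome that differ between the lines could not be told apart from chance, since 72.6% of random gene sets had fewer neighbouring pairs than the 22 found (median 19, highest 36). That count pools all 98 genes and cannot decide for the neonatal calls, so such a stretch remains open for Tdgf1 and Tma7. Both genes lay at background in the gPSC[GSCneonatal] clones and in iPSC[MEF]. Each has a neighbour among the tested genes that was called in other comparisons and not in the neonatal one. Epm2aip1 lies 1 gene from Tdgf1 and Ip6k2 10 genes from Tma7. In iPSC[GSC] against iPSC[MEF], Epm2aip1 differed by 1.33 but its other probes by 0.54 and −0.69, and Ip6k2 by −1.40 and its other probe by −1.04.

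The line gPSC[GSCneonatal] clone 2 resembled iPSC[MEF] (mean r 0.9952 over 4 array pairs) about as closely as arrays of a single line resemble each other (0.9959). Within each batch 12 genes differed at least 2-fold. Arrays of a line within 1 batch differed in 0 genes in each iPSC[GSC] line and 5 in MEF, and arrays of a line in different batches in at most 10, while the next closest line differed in 193. A single RNA deposited under both names would likely differ in no more genes than 2 arrays of a line do, so the 12 genes argue against it, among them Eif2s3y (7.24 against background at 4.30), Erdr1 (6.44 against 4.42), Grb10 (7.55 against 8.78) and Phlda2 (8.46 against 9.58). Whether both are cultures of a single line was not tested, and without it and gPSC[GSCadult] clone 2 the gPSC calls against ESC numbered 38.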
